A study of Mus musculus with 6 samples.

How the data were processed

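RNA of 6 samples of cultured microglia, 3 control and 3 EV-treated, was extracted with Trizol and selected for polyadenylated transcripts, and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The series text gives paired reads of 150 bases and 56000000 to 84000000 reads per sample. Trimmomatic 0.36, STAR, Subread and DESeq2 are listed in the submitters' processing notes, with GRCm38 as the genome build; the settings, the annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, and with no statement that the kit marks strand, reads of overlapping or antisense genes cannot be told apart, and joined entries are uncertain.

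The deposited values are raw counts, whole numbers per exon bin, per the file headers, which give each bin's gene identifier, position, strand and length. Bins of a gene did not overlap each other. The table of the whole series held the same counts as the files of the single samples in all 6 libraries, so it gave no alternative. Of 48005 gene entries, 1194 join 2 or more genes whose exons overlap, and these took 11.3% to 16.5% of the counts. The totals per library are above the stated number of reads. A read that spans several bins may have been counted in each, or the reads of a pair may have been counted singly, which the totals do not tell apart. A gene's sum over bins is therefore not taken as a number of distinct reads. Gene symbols were found for 49298 of 49644 identifiers. In GENCODE vM21 on GRCm38, 49384 of the identifiers were present, and 42581 entries of a single gene had the same start and end there.

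Counts were summed over the bins of each gene entry. Entries with too few counts were removed with filterByExpr, which left 16605, of which 853 join several genes. Libraries were scaled by TMM, with factors of 1.09 to 1.16 in control and 0.855 to 0.921 in EV-treated libraries, and groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) and no covariate, with Benjamini-Hochberg adjustment over all entries tested, a threshold of 0.05 and 2-sided tests. SEs were taken as the log2 fold change divided by the square root of F. CPM values are counts scaled to the usual common total with TMM library sizes. For a gene at 0 in all libraries of a group, a fold is a lower bound against a floor of 3 counts per library (0.0208 CPM on average in control), which covers counting error only. The counts give a common biological coefficient of variation of 0.174.

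Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, for all 37 lists with at least 5 tested genes, adjusted over the lists, with a preset correlation of 0.01 and with an estimated one, and with fry. The list symbols Lrrc33, Zcchc11 and Zcchc6 matched no symbol used here. The rule for named genes, written before the data were examined, took entries with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups, and of these the 12 highest rises and the 12 deepest falls, plus up to 2 rising and 2 falling members of each list with the smallest p. Some genes that the rule takes are not reported here. Unnamed gene models were passed over. The pattern for these was written after values were seen and passed over 1 entry, U90926, with a log2 fold change of 10.70. Tnf, Nfkbia, Tlr2, Tlr4, P2ry12, Trem2, the sex-linked genes and the genes of the closing observations were chosen after their values were seen.

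The gene test, the list tests, DESeq2, limma-voom and the bin usage test were run on simulated data, and the other steps were not. Only the outcome for the gene test is given here. For the gene test, counts were drawn from the mean control levels and the real library sizes and dispersions, with 200 changed genes. Far fewer genes changed there than in these data, and no scaling difference between groups was drawn, so the effect of scaling was not tested. Of 16242 genes run, the test recovered 96% and 100% of genes changed by a log2 of -2 and 2, and 84% and 88% of those changed by -1 and 1, each from 50 genes, and called 14 unchanged genes. No pair of libraries of a group agreed within counting noise (chi-square per degree of freedom of 24.6 to 64.8), so none was taken as a repeat of another; this does not show that they came from separate cultures.

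Alternatives were RLE, upper-quartile and total-count scaling, no filter and a stricter filter (at least 50 counts in at least 3 libraries), DESeq2 1.42.0, limma-voom, the replicate letter as a block, each library left out, an offset for gene length, stricter thresholds, and, for lists, other tests. Chosen after seeing the data were the single bin of each gene with the most counts in place of the sum, entries of single genes alone, and the sex-linked covariate. Bin usage within genes was tested with edgeR's diffSpliceDGE. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for other steps.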

Results

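Messenger RNA was measured by sequencing in cultured microglia, the resident macrophages of the brain, of CD1 mice. One group of 3 samples received extracellular vesicles (EVs), membrane-bound particles that cells release, collected by serial centrifugation from neural stem cells (NSCs) of the subventricular zone, and the other group of 3 samples received the control treatment. The libraries are named by group and by the replicate letter of their titles. Summed over all exon bins, the counts came to 120734562 in control A, 109744701 in control B, 162544804 in control C, 142805303 in EV-treated A, 133112063 in EV-treated B and 139149393 in EV-treated C. These totals exceed the stated number of reads. Whether reads that overlap several bins were counted in each of them, or the reads of a pair singly, is not known. The labels do not say whether the samples of a group came from separate cultures or animals, so p-values measure the spread between these 6 samples, which may be technical.

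The 2 groups were far apart. The Pearson correlation of log2 CPM (counts scaled to a common library total) across genes was 0.985 to 0.993 between libraries of the same group and 0.870 to 0.878 between libraries of different groups, and the first principal component, which separated the groups, held 89.2% of the variance. The 10 most abundant genes took 14.7% to 16.7% of the counts in control libraries and 10.8% to 11.8% in EV-treated libraries. The median relative position of counts along 6234 protein-coding genes, from 0 at the 5' end to 1 at the 3' end, was 0.462 to 0.474 in control libraries and 0.460 to 0.462 in EV-treated libraries.

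The comparison of EV-treated with control microglia asks how the vesicles of NSCs change the transcripts of microglia. The genes Il6, Nos2, Ptgs2, Il12b and Csf3, which encode inflammatory cytokines and enzymes, had 1449 to 1959 times the control level in EV-treated libraries. Il6, which encodes the cytokine interleukin 6, went from 0.382 ± 0.0766 CPM in control to 748 ± 37.02 CPM in EV-treated libraries (SD, n = 3 each). Il1b, which encodes interleukin 1 beta, went from 6.38 ± 0.654 to 8966 ± 761 CPM. Cx3cr1, which encodes the fractalkine receptor of microglia, went the other way, from 336 ± 95.3 to 2.46 ± 0.632 CPM. Of 16605 gene entries tested with edgeR's quasi-likelihood test, 11037 (66.5%) changed at an adjusted p under 0.05, of which 5482 rose and 5555 fell.

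Among the entries that passed, 3394 rose and 3256 fell by at least a log2 change of 1, and 720 rose and 253 fell by at least a log2 change of 4. In 11842 entries (71.3%) the 3 EV-treated libraries lay all above or all below the 3 control libraries, where chance gives 10%. All control libraries were at 0 for 83 of the entries that changed, and all EV-treated libraries for 19. With library totals alone as the scaling, 34.0% of the 11495 calls were rises, against 49.7% with TMM scaling, and the median log2 fold change of all genes was -0.38 in place of -0.02; with upper-quartile scaling it was -0.14 and 44.1% of the calls were rises. The fold changes given here are relative to the TMM scale.

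**Figure D1:**
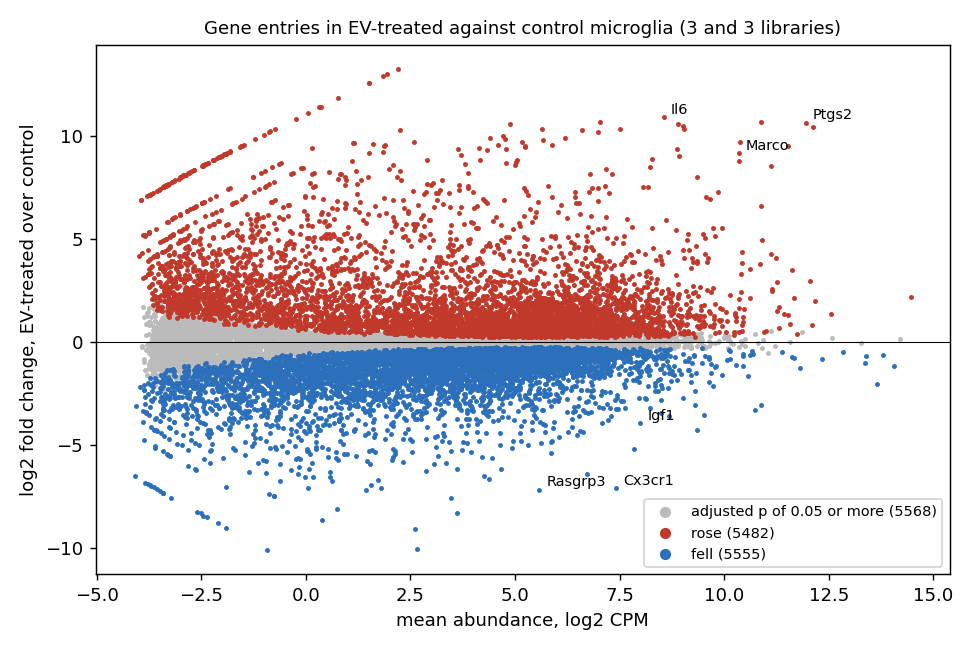
Each point is 1 of 16605 gene entries, with its mean abundance in log2 CPM on the horizontal axis and its log2 fold change of EV-treated over control libraries on the vertical axis (3 libraries each). Red points rose (5482), blue points fell (5555) and grey points had an adjusted p of 0.05 or more (5568).

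The 12 genes with the highest rise under the naming rule had log2 fold changes of 9.92 to 10.92. Il6 (ENSMUSG00000025746, GRCm38 chromosome 5, 30013114 to 30019981, plus strand) led with a log2 fold change of 10.92 (SE 0.20, adjusted p = 1.06e-09). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254, plus strand), the inducible nitric oxide synthase, followed with 10.67 (SE 0.21). Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227, plus strand), the inducible cyclooxygenase of prostaglandin synthesis, rose by 10.65 (SE 0.20) and reached 7859 ± 892 CPM. The cytokine genes Il12b (10.59), Csf3 (10.50) and Il1b (10.46) and the chemokine gene Cxcl1 (10.33) were in the same range. Vnn3 (10.37), the placental growth factor gene Pgf (10.33), the incretin receptor gene Gipr (10.32) and the adrenomedullin gene Adm (10.23) rose as steeply. The entry that joins Serpinb2 and Serpinb10, whose exons overlap in the counting, rose by 9.92, and its share per gene is uncertain.

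The genes with the deepest fall under the same rule had log2 fold changes of -7.18 to -5.50. Rasgrp3 (ENSMUSG00000071042, chromosome 17, 75435905 to 75529043, plus strand), a guanine nucleotide exchange factor for Ras, had a log2 fold change of -7.18 (SE 0.29, adjusted p = 3.76e-08). Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, minus strand) had -7.09 (SE 0.31, adjusted p = 5.92e-08). Hpgd, whose enzyme breaks down prostaglandins, had -6.51. Cd300lb (-6.41), Plekhh2 (-6.16), the kinase gene Matk (-6.16) and Slc9a3r2 (-5.93) also fell. The cannabinoid receptor gene Cnr2 (-5.87), the RNA sensor gene Tlr8 (-5.60), the peroxisomal transporter gene Abcd2 (-5.59) and Rtn4rl1 (-5.50) fell as well.

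**Figure D2:**
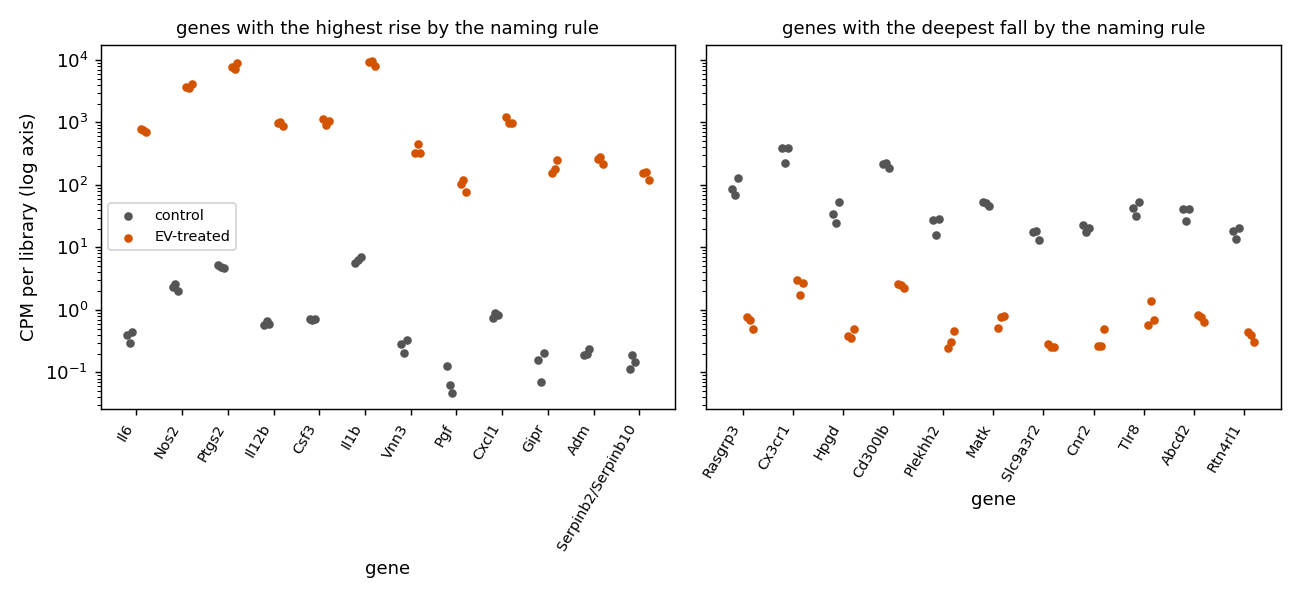
Each point is the CPM of 1 library on a log axis, for genes with the highest rise (left) and the deepest fall (right) under the naming rule, with 3 control libraries in grey and 3 EV-treated libraries in orange. In each gene shown the 2 groups do not overlap; Il6 goes from 0.382 to 748 CPM on average and Cx3cr1 from 336 to 2.46 CPM.

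Of 37 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 placed 9 above and 3 below the other genes at an adjusted p under 0.05. With an estimated correlation no list had an adjusted p under 0.05, and 4 had an unadjusted p under 0.05; fry's directional test called 30. Counts of members adjusted over the list alone are given where they differ from the counts over all genes, which was so for 10 lists.

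Cytokine and chemokine genes rose together. The inflammatory cytokine list also holds the enzyme genes Nos2 and Ptgs2 and the growth factor gene Vegfa. Of 23 inflammatory cytokine genes tested, 22 rose and none fell, with a median log2 fold change of 7.60, or 5.84 with genes at 0 in all controls set to their lower bound (camera adjusted p = 6e-11; adjusted p = 0.0788 with an estimated correlation). The exception was Csf1, the macrophage growth factor gene, at -0.28 (SE 0.27), or 0.12 without control replicate C. It had -0.99 (SE 0.22, edgeR adjusted p = 0.00467) with the sex-linked covariate and -0.35 (edgeR adjusted p = 0.0301) without a filter. Tnf, at 3.57 (SE 0.17), rose less than Il12b and Csf3. Of 22 chemokine genes 20 rose and 1 fell, with a median of 4.70 (camera adjusted p = 1.43e-06; adjusted p = 0.419 with an estimated correlation). Cxcl2 rose by 9.71 (SE 0.26), while Cxcl14 fell, at -2.11 (SE 0.16). Ccl6 had -0.55 (SE 0.44), with an adjusted p of 0.0354 and a log2 fold change of -0.94 without control replicate A, and 0.18 without control replicate B. All 24 genes of NF-kB feedback, which encode inhibitors and targets of this inflammatory transcription factor, rose, with a median of 2.94 (camera adjusted p = 2.04e-10; adjusted p = 0.207 with an estimated correlation). With library totals alone 22 of these genes rose and 0 fell. Ier3 rose by 8.53, Ccrl2 by 6.95 and the inhibitor gene Nfkbia went from 38.9 ± 3.77 to 622 ± 31.7 CPM.

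Interferon-stimulated and MHC class I genes rose as well. Of 32 interferon-stimulated genes 29 rose and 1 fell, with a median of 1.90 (camera adjusted p = 6.75e-08; adjusted p = 0.564 with an estimated correlation). With library totals alone 27 of these genes rose and 1 fell. The antiviral gene Rsad2 rose by 5.06 (SE 0.20) and the entry of Herc6, joined with 2 other genes, by 2.96, while Ifit3b fell, at -1.77 (SE 0.27). The values of Ifit3b and H2-Q6 are uncertain, since close paralogs share their sequence. Of 17 MHC class I genes 13 rose and none fell, with a median of 1.29 (camera adjusted p = 0.0011; adjusted p = 0.564 with an estimated correlation), among them the peptide transporter gene Tap1 (1.90) and H2-Q6 (2.78). With library totals alone 11 MHC class I genes rose and 0 fell. Of 14 genes of the MHC class II list, which includes the co-stimulatory gene Cd86, 8 rose and 5 fell (camera adjusted p = 0.162). H2-Ab1 rose by 3.93 and Cd86 by 3.57, while H2-DMb2 (-3.38) and H2-DMb1 (-1.80) fell.

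Genes of glycolysis and of the response to hypoxia had a median log2 fold change of 3.31. Of 29 tested, 28 rose and 1 fell (camera adjusted p = 1.59e-12; adjusted p = 0.214 with an estimated correlation). Adm and the oxygen sensor gene Egln3 (7.26, SE 0.15) rose most clearly, and the carbonic anhydrase gene Car9 fell, at -0.99 (SE 0.15). Of 34 oxidative phosphorylation genes 3 rose and 12 fell (2 and 11 adjusted over the list alone; 0 and 22 with library totals alone), with a median of -0.17 (camera adjusted p = 0.334). Their median difference of log2 CPM, -0.18 over all libraries, was -0.33 without control C, -0.31 without EV-treated B, -0.09 without EV-treated C and 0.07 with the sex-linked covariate. Ndufs1 fell, at -0.83, while Cox5a rose by 0.67, with an adjusted p of 0.0523 when library totals alone set the scale. Antioxidant genes of the NRF2 pathway rose in 14 of 24 cases and fell in 4 (15 and 4 adjusted over the list alone; 13 and 8 with library totals alone), with a median of 1.17 (camera adjusted p = 0.0167; adjusted p = 0.643 with an estimated correlation). The cystine transporter gene Slc7a11 rose by 4.21 and the heme oxygenase gene Hmox1 by 4.07, and Mgst1 (-1.19) fell. Of 26 genes of endoplasmic reticulum stress 15 rose and 4 fell (13 and 7 with library totals alone, median 0.35), with a median of 0.72 (camera adjusted p = 0.0167; adjusted p = 0.638 with an estimated correlation), led by Ppp1r15a (3.17) and Sesn2 (1.97), while Phgdh (-1.02) fell.

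Immediate early genes split. Of 28, 18 rose and 8 fell, with a median of 1.16 (camera adjusted p = 0.0202; adjusted p = 0.347 with an estimated correlation). The orphan receptor gene Nr4a3 rose by 7.47 (SE 0.21), while Egr2 (-4.86) and Fos (-2.54), both fast-responding transcription factor genes, fell.

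Genes typical of resting microglia fell. Of 24 homeostatic microglia genes 18 fell and 2 rose (19 and 2 adjusted over the list alone), with a median of -1.86 (camera adjusted p = 0.000148; adjusted p = 0.469 with an estimated correlation). Cx3cr1 and the phagocytic receptor gene Mertk (-4.32, SE 0.20) fell, and P2ry12, a purinergic receptor gene, had 3.77 ± 1.14 CPM in control and 0.0885 ± 0.0334 CPM in EV-treated libraries. Sall1, a transcription factor gene of microglial identity, rose by 0.84 (SE 0.14), and Bin1 rose by 0.59, with an adjusted p of 0.0745 when library totals alone set the scale. Of 27 genes of disease-associated microglia 16 fell and 6 rose, with a median of -0.67 (camera adjusted p = 0.0525). This p was 0.04 without control A, 0.0346 without control B or control C, 0.0508 without EV-treated A, 0.0454 without EV-treated B, 0.107 without EV-treated C and 0.0496 with RLE scaling. Trem2, a lipid receptor gene, fell from 1342 ± 148 to 115 ± 20.01 CPM and Igf1 had a log2 fold change of -3.93, while Cst7 rose by 2.70 and the ferritin gene Fth1 by 2.20.

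Phagocytosis and cell cycle genes fell. Of 23 genes of phagocytosis and the uptake of dying cells 16 fell and 4 rose (17 and 4 adjusted over the list alone), with a median of -1.41 (camera adjusted p = 0.0097; adjusted p = 0.419 with an estimated correlation). The bridging protein gene Pros1 had -3.87, whereas the scavenger receptor gene Marco rose by 9.16 (SE 0.24) and Itgb3 by 2.16. Of 38 cell cycle genes 29 fell and 6 rose, with a median of -1.30 (camera adjusted p = 0.0011; adjusted p = 0.565 with an estimated correlation). Rrm2 (-3.69) and Mcm3 (-1.60), both needed for DNA synthesis, fell, and the proliferation marker gene Mki67 (2.42) and the mitotic checkpoint gene Bub1 (2.55) rose.

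**Figure D3:**
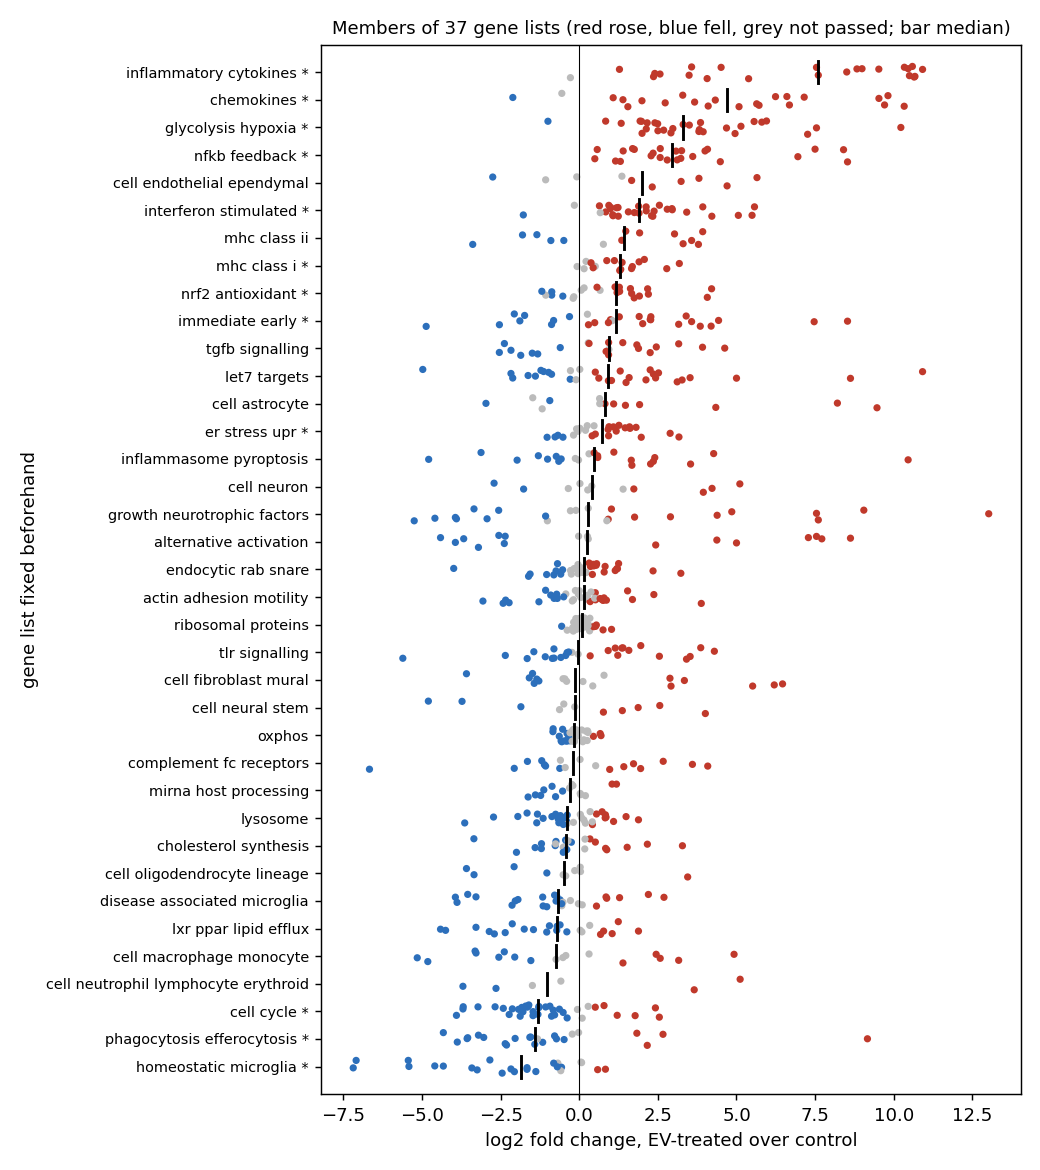
Each point is the log2 fold change of 1 gene, EV-treated over control (3 libraries each), in 37 gene lists ordered by their median, which a black bar marks. Red genes rose, blue genes fell, grey genes did not pass, and an asterisk marks the 12 lists called by camera with a preset correlation; the medians run from -1.86 (homeostatic microglia) to 7.60 (inflammatory cytokines).

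Several immune and lipid lists held strong changes both ways and were not called. Of 27 Toll-like receptor pathway genes 13 rose and 12 fell (13 each adjusted over the list alone; median -0.03, mean 0.41, camera adjusted p = 0.61): Irak3 (3.86), Traf6 (3.53) and Tlr2 (3.41) rose, and Tlr8 (-5.60), Tlr13 (-2.35) and Tlr4 (-0.85) fell. Of 23 inflammasome and pyroptosis genes 12 rose and 8 fell (9 and 10 with library totals alone; camera adjusted p = 0.493), with Nlrp3 at 4.27 and its adaptor gene Pycard at -4.78. Of 18 complement and Fc receptor genes 7 rose and 7 fell (8 and 7 adjusted over the list alone; median -0.21, mean 0.09, camera adjusted p = 0.891), with C3 at 4.09, Fcgr2b at 3.60 and C1qc at -1.64. Of 17 genes of alternative activation 7 rose and 7 fell (camera adjusted p = 0.509), with Socs3 at 7.29 and Stab1 at -3.20. Of 23 genes of lipid efflux under the receptors LXR and PPAR 15 fell and 5 rose, with a median of -0.71 (camera adjusted p = 0.0579, and 0.04, 0.0259, 0.0429 and 0.0483 without control A, B or C or EV-treated A, and 0.0494 with the sex-linked covariate); the lipoprotein lipase gene Lpl fell, at -3.28, and Acsl1 rose by 1.89. Of 24 cholesterol synthesis genes 11 fell and 7 rose (13 and 7 adjusted over the list alone; 14 and 5 with library totals alone and 13 and 5 with upper-quartile scaling; camera adjusted p = 0.509), with Dhcr7 at -3.35 and Sqle at 3.28. Of 34 lysosome genes 17 fell and 9 rose (18 and 9 adjusted over the list alone; camera adjusted p = 0.339), with the lysosomal regulator gene Tfeb at -3.64 and Lipa at -2.72 against Ctsc at 1.88. Median differences of log2 CPM turned sign with 1 library left out for the Toll-like receptor list (-0.03 over all libraries; 0.10 without control C, 0.02 without EV-treated A and without EV-treated C) and, without control C, for the complement (-0.22 to 0.02) and alternative activation (0.29 to -0.01) lists.

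Among trafficking, growth factor and RNA lists camera with the preset correlation called no shift either. Of 35 endocytic Rab and SNARE genes 15 rose and 9 fell (8 and 16 with library totals alone; camera adjusted p = 0.547), with Ehd1 at 3.23 and Flot1 at -1.61. Of 36 genes of actin and adhesion 12 rose and 11 fell (9 and 18 with library totals alone; median 0.14, mean -0.01, camera adjusted p = 0.891), with Fscn1 at 3.88 and Myo1f at -3.06. Of 23 growth factor genes 10 rose and 8 fell (camera adjusted p = 0.7), with Inhba at 9.05, the vascular growth factor gene Vegfa at 7.54, Pdgfb at -3.34 and Igf1 at -3.93. Of 21 TGF-beta pathway genes 12 rose and 7 fell (camera adjusted p = 0.315), with Id2 at 2.45 and the receptor gene Tgfbr1 at -2.17. Of 31 known targets of the let-7 microRNA 18 rose and 10 fell (camera adjusted p = 0.146), with Ccnd1 at -4.97 and the cytokine signalling inhibitor gene Socs1 going from 0.91 ± 0.0591 to 29.2 ± 3.24 CPM. Of 15 microRNA processing and host genes 7 fell and 2 rose (camera adjusted p = 0.266), with Dicer1 at -1.39 and Ago2 at 1.05. Of 45 ribosomal protein genes 5 rose, 1 fell and 39 did not pass (2 and 0 adjusted over the list alone; camera adjusted p = 0.509), and their median of 0.11 was -0.27 with library totals alone (2 rose and 13 fell) and -0.02 with upper-quartile scaling (3 and 2). With the ratio of Y-linked to X-linked counts as a covariate this list was called as risen (camera adjusted p = 0.00861, median 0.46). With library totals alone the medians of the actin (-0.23), alternative activation (-0.10), endocytic (-0.23) and growth factor (-0.08) lists also turned negative. The endocytic list's median difference of log2 CPM went from 0.13 to -0.01 without control C, and that of the ribosomal list from 0.09 to -0.08 without control C and -0.07 without EV-treated B.

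Markers of other cell types moved both ways. Summed over each list, CPM fell from 992 ± 355 to 347 ± 84.95 for fibroblast and mural markers (SD, n = 3 each). It fell from 381 ± 109.6 to 72.75 ± 6.62 for oligodendrocyte lineage markers, mostly through Cspg4, on both lists. Macrophage and monocyte markers went from 1802 to 895 CPM. Astrocyte (84.3 to 149 CPM), neuronal (15.5 to 44.1) and neutrophil, lymphocyte and erythroid (11.7 to 29.8) sums rose. Whether the share of these cells differed between groups was not tested. Of 11 NSC markers tested 5 rose and 3 fell (median -0.14, mean -0.09, camera direction up, adjusted p = 0.736): Nes went from 68.5 ± 19.9 to 2.47 ± 0.668 CPM and Fabp7 from 11.7 ± 7.17 to 0.888 ± 0.458 CPM, while Egfr rose from 0.523 to 3.09 CPM. The median difference of log2 CPM of this list, 0.15 over all libraries, was -0.29, 0.23 and 0.85 without control A, B or C and 0.25, -0.43 and -0.18 without EV-treated A, B or C. Of 13 astrocyte markers 7 rose and 2 fell (4 and 2 with library totals alone; camera adjusted p = 0.286); the glutamate transporter gene Slc1a2 rose from 0.0952 ± 0.0805 to 74.8 ± 17.7 CPM and the gap junction gene Gja1 from 0.0943 to 29.1 CPM. Of 10 oligodendrocyte lineage markers 4 fell and 1 rose (camera adjusted p = 0.339), with Mbp at -2.07 and the entry of Pdgfra, joined with a microRNA gene, at 3.45. Of 11 neuronal markers 4 rose and 2 fell (camera adjusted p = 0.352), with Slc17a7 reaching 1.26 ± 0.421 CPM. Of 18 fibroblast and mural cell markers 6 rose and 6 fell (median -0.14, mean 0.92, camera adjusted p = 0.631). Cspg4 was at -3.58 (291 to 24.3 CPM) and Foxc1, far less abundant, at 6.20 (0.0721 to 5.57 CPM). Their median difference of log2 CPM, -0.03 over all libraries, was -0.15, 0.07 and 0.43 without control A, B or C and 0.51, -0.27 and -0.01 without EV-treated A, B or C. Of 10 endothelial and ependymal markers 6 rose and 1 fell (6 and 3 with library totals alone; camera adjusted p = 0.0674, and 0.0341 with the stricter filter), with Abcb1a at 4.70 and Flt1 at -2.75. Of 17 macrophage and monocyte markers 8 fell and 5 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.51), with Mrc1 at -2.55 and Cd38 at 4.92. Of 6 neutrophil, lymphocyte and erythroid markers 2 rose and 2 fell (median -1.03, mean 0.06, camera adjusted p = 0.771), with S100a8 at 3.66 and Cd4 at -2.64.

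Sex-linked genes differed between the groups. Y-linked genes fell: Uty went from 7.38 ± 2.69 to 3.67 ± 1.06 CPM, and log2 fold changes were -1.19 (SE 0.25) for Ddx3y, -1.31 (SE 0.30) for Eif2s3y and -2.13 (SE 0.29) for Kdm5d, while the entry of Xist, the RNA that silences one X chromosome in female cells, joined with 2 other genes, rose by 1.51 (SE 0.36). Without EV-treated replicate A, Uty had an adjusted p of 0.0571. Summed over the 4 Y-linked genes, CPM was 55.2, 48.5 and 23.8 in control A, B and C and 15.7, 17.4 and 18.6 in EV-treated A, B and C, so control C lay nearer to the EV-treated libraries than controls A and B did. Among the X-linked paralogs Ddx3x fell, at -0.96 (SE 0.12), and Kdm5c rose by 1.01 (SE 0.12). With the log2 ratio of Y-linked to X-linked paralog counts as a covariate, whose slope within groups rests mostly on control C, 8793 entries changed, and 8548 of them also changed in the same direction without it.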

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

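The single best-covered bin, single-gene entries and the sex covariate were chosen after seeing the data, and the cause of a change was not tested unless stated. With a log2 change of at least 1, which asks for more, 6650 entries passed, and 9138 did at an adjusted p of 0.01; under all other settings 8793 to 11942 changed, and 10190 (without EV-treated A) to 10918 (without EV-treated B) with 1 library left out. Calls shared with the reported result had the same direction under each scaling, filter, tool, length or block setting and left-out library; exceptions came with the best-covered bin (9634 of 9676 kept it) and the sex covariate (8548 of 8551). Correlations of deviations were 0.035 (A), 0.167 (B) and 0.21 (C) for the same letter and -0.199 to 0.0341 for different letters, so each sample correlated best with its own letter, a hint of pairing from the data, and the second principal component ordered the letters alike in both groups. With A under 0.1 and no label on it, the letters were not taken as pairs. File names number control A to C as 2 to 4 and EV-treated A to C as 1 to 3; by those numbers control A goes with EV-treated B (0.00973) and control B with EV-treated C (-0.199). The replicate block called 11609 entries, or 11749 with the length offset, and 12 lists. Of the 37 lists 0 were called with an estimated correlation and 30 with fry, which asks another question; other settings called 12 to 14. The lowest correlation within a group and the highest between groups were 0.981 and 0.82 with the best-covered bin, and nearest without a filter, at 0.984 and 0.952. The table of the whole series was identical and gave no value; groups of 3 were not tested for outlying samples.

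Among lists and named genes, directions turned only in those that had not passed, Rps15 excepted. Medians where a list's test direction turned were 0.14 for actin and -1.11 for neutrophil and lymphocyte markers with fry, and 0.17 for actin, 0.031 for cholesterol synthesis, -1.0003 for NSC and -0.43 for fibroblast markers with the sex covariate. With 1 library left out they ran from 0.0519 to 0.145 for actin, -0.38 to 0.0185 for complement and -0.0775 to 0.24 for ribosomal proteins. Myrf had -0.0873 with upper-quartile scaling, -0.33 with library totals, -0.0426 without a filter, -0.12 with the length offset, -0.0825 with block and length offset and -0.15 with the best-covered bin, and Olfr99 had -0.14 with library totals. The sex covariate gave 0.13 for Psmb10, 0.03002 for Rps15, 0.12 for Rps19 and -0.0923 for Olfr113. With 1 library left out values ran from -0.49 to 0.12 for Csf1, -0.94 to 0.18 for Ccl6, -0.66 to 0.14 for Mx1, -0.31 to 0.10 for Psmb10, -0.14 to 0.19 for Myrf, -0.125 to 0.023 for Eif2s3x, -0.237 to 0.0444 for Kdm6a and -0.48 to 0.18 for Olfr111. Depth limits genes near the floor, where a few counts decide.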

Other observations

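The tests of gene families, olfactory receptors, bin usage, NSC marker sums, library scaling, ligands and sex-linked genes were chosen after the values were seen. The tests on the side of a neighbour gene (after a trend with distance had been seen), on microRNA words and on other splits were written before their results were seen, but the demand that the spread of a word's percentile also stay above 2.5 was added after the percentiles had been seen. A first test of the sex mix, which set control C against controls A and B, was replaced after its value was seen, since a single library excludes nothing, and so was a fit with the Y to X ratio as a covariate, whose slope within groups rests mostly on control C. In that fit all 22 of the 22 risen genes of the cytokine list kept an edgeR adjusted p under 0.05. In the first test the median log2 difference was 0.00713 over genes that rose, against 1.33 between the groups, and 0.00445 over genes that fell, against -1.19.

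Olfactory receptor genes rose in a block next to a strongly induced MHC gene. Of 122 families of gene symbols with at least 12 tested protein-coding members, 9 differed from the other genes in log2 fold change at an adjusted p under 0.05 (Mann-Whitney test across genes, which are not independent replicates). The Olfr family had the smallest p, with 12 of 20 members risen and none fallen (median 1.35, and 1.23 with upper-quartile scaling, adjusted p = 3.21e-05). Several of these members were near 0 in control, such as Olfr130 (0.00354 CPM), and could pass the abundance filter only through the EV-treated libraries. Members low in both groups were not tested, so the filter itself favours rises here and this p is no support for them. Outside the 20, the entry Olfr369-ps1 fell, at -2.23 (edgeR adjusted p = 0.0445). On chromosome 17 of GRCm38, H2-M2 (37480851 to 37483552, minus strand) rose from 11.3 ± 4.46 to 1496 ± 198 CPM. Of 15 Olfr entries between 37279043 and 38134526, 11 rose. Past the 3' end of H2-M2, log2 fold changes were 5.80 for Olfr109 (0.0191 to 1.16 CPM), 6.83 for Olfr107 (0.00516 to 0.62 CPM) and 6.59 for Olfr105-ps. The nearest entries before its 5' end moved less, with Olfr110 at 1.12 and Olfr112 at 1.96. There Olfr111 had 15.3 CPM in control and 14.2 CPM in EV-treated libraries (edgeR adjusted p = 0.757). Farther out the order differed, with Olfr129 (4.88) and Olfr130 (5.16) on the 5' side and Olfr99 (0.22) past the 3' end. Whether reads running past the end of H2-M2 entered these entries was not tested. The window was drawn around this block after it was seen. Genes of zinc finger proteins (Zfp) went the other way, with 144 of 336 fallen and 75 risen (median -0.33), or 195 and 52 with library totals alone (median -0.70), and of 20 Nudt genes 14 fell and 2 rose (family adjusted p = 0.000103 and 0.035). Histone genes (Hist) rose in 12 of 21 cases and fell in 2 (family adjusted p = 0.0131), in libraries selected for polyadenylated RNA. No median of these 4 families changed sign under another scaling.

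The share of counts per exon bin within genes changed too. In 2746 of 9191 protein-coding genes tested the share of some bins differed between the groups at an adjusted p under 0.05 (diffSpliceDGE). Since the strand setting is not given, reads of overlapping genes may enter these calls. How many of the 2746 reflect changed exon use was not tested. A bin of LTO1 (chromosome 7, 144931420 to 144931701, plus strand) fell in share. This bin lies within the span of Ccnd1, on the minus strand, which had a log2 fold change of -4.97. A bin of Sh3bp1 that rose in share lies in 0 of 9 annotated transcripts. In Cp, the ceruloplasmin gene, which itself rose by a log2 of 5.02, the last exon of 1 transcript, all 3' UTR (chromosome 3, 20008540 to 20009145), fell from 36.2% ± 3.99 to 0.48% ± 0.0456 of the gene's counts (SD, n = 3). In Triobp a coding exon of 2293 bases (chromosome 15, 78966294 to 78968586), present in 3 of 12 annotated transcripts, rose from 0.0521% ± 0.0474 to 15.1% ± 2.75. In Shisa3 the exon with the end of the coding part and 3' UTR (chromosome 5, 67611036 to 67613992) rose from 0.537% ± 0.71 to 56.7% ± 5.54.

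The cytokine rise was set against 3 explanations. Scaling is argued against by the median of the cytokine list, 7.24 with library totals alone. A microbial ligand such as endotoxin in the vesicle preparation may also act, since 29 of 32 interferon-stimulated genes and all 24 NF-kB feedback genes rose. With library totals alone 27 and 22 of them rose. Such a ligand cannot be told apart from the vesicles because both went to the same samples. For messenger RNA carried in from NSCs the marker values cannot decide, since the ratio of cytokine to marker RNA in the vesicles was not measured. The sum of NSC markers, without Vim and Notch1, which macrophages also express, was at most 14.6 CPM in EV-treated and at least 58.8 CPM in control libraries. Nes made up 80.1% of the mean control sum, so the fall of the sum by itself excludes nothing. What remained in EV-treated libraries caps the marker RNA that was carried in, including Egfr and Prom1 (0.0557 to 0.895 CPM), which rose. The genes of the cytokine list summed to 193 ± 50.8 CPM in control and 30380 ± 759 CPM in EV-treated libraries (SD, n = 3 each). RNA of the vesicles themselves was not measured. A direct effect of the vesicles stays open as well.

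The sex-linked difference was set against the mix of cells. A smaller share of male cells in the EV-treated samples may account for Ddx3y, Uty and Eif2s3y, whose ratios to each other shifted between groups by at most 0.22 on the log2 scale, within a range of 1.07 inside a group. For Kdm5d it is argued against as the whole cause, since its ratio to the other genes shifted by -0.97, beyond a range of 0.284. Their X-linked paralogs moved as well, Ddx3x by -0.96 (SE 0.12), about as far as Ddx3y at -1.19 (SE 0.25), and Kdm5c by 1.01 (SE 0.12). A smaller male share would not lower Ddx3x, so an effect of the vesicles on the sex-linked genes stays open. A larger share of female cells alone would raise a gene no more than that share rose, for which Xist, at most a log2 of 2.59 between any 2 libraries of the groups, is the measure if its level per cell was constant. Of the 22 genes of the cytokine list that rose, 18 lay above this value by more than 2 SE. For Il12a and Il1f6, at 0 in all controls, the lower bounds were used. This argues against the sex mix as the whole cause for these 18. For Il18, Il27, Ebi3 and Il15, the other 4, the sex mix cannot be told apart from the treatment.

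Fold changes of genes below 1 CPM followed those of the nearest gene above 5 CPM, with a Spearman coefficient across genes of 0.606 where they overlapped and 0.119 where they were over 100 kb apart. Reads running past the 3' end of the neighbour are argued against as the whole cause: up to 20 kb the coefficient past the 3' end was lower than that before the 5' end, by -0.13 (95% bootstrap interval -0.228 to -0.0316). These coefficients are taken over all such genes and do not decide single cases such as the block beside H2-M2. Regulation shared by neighbouring genes is a candidate explanation, since the coefficient before the 5' end was 0.321 (0.251 to 0.387), above the interval of distant genes, which ended at 0.189. For overlapping genes, reads of introns of the expressed gene were not tested, so part of the rise of low-abundance markers of other cells may have that source.

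A hypothesis was that microRNAs carried by vesicles lower messenger RNAs with matching 3' UTR words, which was tested across 10120 genes after adjusting for UTR length, base content and abundance. Among words found in a similar number of genes, the difference of genes with the word lay at percentile 8.72 for let-7, 10.6 for miR-9, 97.7 for miR-26 and 93.6 for miR-181. For miR-26 (difference 0.09, 95% interval 0.01 to 0.19) and miR-181 (0.06, -0.01 to 0.14) this argues against an average lowering beyond that of like words. A lowering of only some genes with the word was not tested. For let-7 and miR-9 the percentile met the bound written beforehand against a lowering, 2.5 or above, but its spread reaches below it, so the test does not decide. The word of miR-155, a microRNA induced in activated macrophages, lay at percentile 3.08, which does not decide either, although the difference of -0.10 had an interval below 0 (-0.20 to -0.00237).

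The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With edgeR the real split called 11037 entries, and 1 split, the real one, called as many. The highest of the others called 0, with 24 to 256 entries at an unadjusted p under 0.05. Each of those mixes control and EV-treated libraries, so the group difference enters the spread within each side. Few calls follow from that, and these counts are no measure of chance.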
